A study of Psychotria grandis and Psychotria costivenia and Psychotria revoluta with 6 samples.

How the data were processed

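Leaf mRNA was measured in 6 libraries, 1 per plant, from 3 shrub species of the genus Psychotria sampled in Cuba, with 2 plants per species. Per the labels, P. grandis and P. costivenia are nickel hyperaccumulators and P. revoluta is a non-accumulator. The plants grew wild in gallery forest on serpentine soil. Per the labels' protocols, leaves were kept in RNAlater, total RNA was treated with DNase, and stranded polyA libraries were made with an Illumina TruSeq kit. Per the series design text, reads were paired-end, and the P. grandis transcriptome, assembled de novo from 1 plant, served as the reference for all 3 species.

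The deposited values are raw read counts per contig, 1 table per plant, per the file headers. A contig is an assembled transcript, so that a gene may be split over several contigs. The assembler, the aligner, the counting tool, the treatment of reads that match several contigs and the use of strand are not given in the sources used here, so counts of near-identical or overlapping contigs are uncertain. All tables listed the same 45143 contigs under running numbers that carry no gene name, sequence or annotation. The gene lists fixed before the data were examined (metal transporters, metal ligands, iron, sulfur and others) could therefore not be applied, and contigs are reported by number. The count columns of both P. revoluta libraries carry a species prefix in the header that differs from the label of the sample. The species given here is that of the labels. The labels date P. revoluta plant 1 to July and the other plant of that species to June, and the date was used as given.

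Library totals ran from 45676087 counts in P. grandis plant 2 to 57907913 in P. revoluta plant 1. A count of 0 allows up to 3 counts, which corresponds to 0.0518 to 0.0657 CPM (counts scaled by the library total to the usual common total) in a single library and to 0.0281 to 0.0316 CPM over both plants of a species. These floors, and all binomial intervals (exact, Clopper-Pearson), cover counting error only, because reads without molecular identifiers are not independent molecules. The plants of a species differed by far more than sampling noise: a chi-square statistic per contig of 759.9 for P. grandis, 104.2 for P. costivenia and 66.1 for P. revoluta, where sampling alone would give about 1. No library was counted as a copy of another.

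The design, the tests, the thresholds, the rule for named contigs and all alternatives except those named as added were chosen before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Contigs were kept by filterByExpr with species as the group and its defaults (minimum count 10, minimum total 15), which left 35660 contigs, 79.0% of the contigs and 99.9% of the counts. Libraries were scaled by TMM, and 1 quasi-likelihood model (glmQLFit and glmQLFTest, robust) with species as the factor was fitted to all 6 libraries, with 3 residual and a median of 2.43 prior degrees of freedom. The 3 contrasts between species were tested two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Contigs apart in a species were those past the threshold with the same sign against both other species. The SE of a log2 fold change was approximated as its absolute value over the square root of the quasi-likelihood F. Fold changes are on the TMM scale, and levels are given as CPM of the library total with the SD over 2 plants. For medians and 4-fold counts over called contigs, a contig with 0 counts in both plants of the lower species had its fold computed against 3 counts over that species. Such a fold is a lower bound. Medians over all tested contigs and correlations of fold changes used the edgeR fits as they were.

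The rule named the contigs with the largest fold changes in the same direction against P. revoluta in both hyperaccumulators, 2 in each direction, among those past the threshold in both contrasts with a log2 CPM of at least 3, at least 4 counts over each lower species and no overlap of libraries. As 0 contigs met it, the rule was applied to P. costivenia against P. revoluta alone, a change made after the values were seen. There, 1565 higher and 792 lower contigs qualified.

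Libraries were compared by the Pearson and Spearman correlation of log2(CPM + 1) across contigs, which are not independent replicates, and by principal components. Contigs without reads in a species had 0 counts in both of its plants and at least 10 counts in both plants of another. A count chosen after the data were seen took contigs for which both plants of a species lay at least 4-fold above or below all other 4 plants on the scale of TMM-scaled CPM + 1. Comparisons that share the P. revoluta libraries were set beside 20 simulated data sets in which neither hyperaccumulator differed from P. revoluta. The 2 P. revoluta libraries were not split, since each comparison would then have rested on 1 of them.

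The test was checked on counts simulated for the 35660 contigs from the means, totals and spread of the real libraries. With 200 changed contigs, the model of 6 libraries recovered 0% at log2 changes of 1, 2 and 4 in each of the 3 comparisons. With 6000 changed contigs, it recovered 2.7%, 16.1% and 66.6% at these sizes for P. grandis against P. revoluta (100 false calls), 0.1%, 7.15% and 67.0% for P. costivenia against P. revoluta (19 false calls), and 3.25%, 17.5% and 69.6% for P. grandis against P. costivenia (119 false calls). The model of the P. costivenia and P. revoluta libraries alone recovered 0%, 40.9% and 75.8% with 200 changed contigs (30 false calls) and 23.1%, 73.1% and 95.4% with 6000 (180 false calls). With 4 libraries and 6000 changed contigs, P. grandis against P. revoluta recovered 0% at each size and P. grandis against P. costivenia 0.1%, 0.8% and 26.2%, and with 200 both recovered 0%. The number of calls thus depended on how many contigs changed and on which libraries shared the estimate of the spread.

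The alternatives were RLE size factors, library totals without TMM, DESeq2 1.42.0 without independent filtering, limma-voom (limma 3.58.1), no low-count filter, a mean of at least 10 CPM, reads in all 6 libraries, a replicate block, models of the 4 libraries of each pair of species, an adjusted p of 0.01, a test against a 2-fold change (glmTreat), thinning to equal depth, and leaving out each library in turn. For correlations they were log2(CPM + 0.1) and the tested contigs alone, and for contigs without reads a minimum of 50 counts. Added after the data were seen were leaving out P. grandis plant 2 and P. revoluta plant 2 together, leaving out contigs read in P. grandis plant 1 and P. revoluta plant 2 alone, at most 3 counts in place of 0, and the alternatives of the 4-fold count. P-values measure the spread between individual plants of a species at 1 locality, shared over all 3 species in the main model. The P. grandis plants therefore also set the spread used for P. costivenia against P. revoluta. Within P. revoluta the spread includes the different collection dates. A fit without 1 library left its species with 1 plant, so that the spread came from the other species.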

Results

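The series set leaf transcripts of 2 nickel hyperaccumulators, P. grandis and P. costivenia, beside those of the non-accumulator P. revoluta. Hyperaccumulators are plants that hold metal in their leaves at levels toxic to most other species. Each species was represented by 2 wild plants. P. grandis and P. revoluta came from Mil Cumbres, P. grandis and P. revoluta plant 2 on 27 June 2014 and P. revoluta plant 1 on 27 July 2014, and both P. costivenia plants came from La Coca on 12 June 2014. Library totals were 50552919 and 45676087 counts for P. grandis plants 1 and 2, 46760513 and 48322940 for P. costivenia, and 57907913 and 48791330 for P. revoluta. Of the 45143 contigs of the P. grandis reference, 45142 had reads in P. grandis plant 1, against 37455 in P. grandis plant 2, 36216 and 35362 in the P. costivenia plants, and 35465 and 38589 in the P. revoluta plants.

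The plants of P. costivenia resembled each other closely, as did those of P. revoluta, and those of P. grandis did not. Across contigs, Pearson's r of log2(CPM + 1) was 0.974 between the P. costivenia plants, 0.989 between the P. revoluta plants and 0.851 between the P. grandis plants (Spearman's rho 0.957, 0.967 and 0.810). P. grandis plant 2 correlated with the P. revoluta plants at 0.960 and 0.963, above its correlation with P. grandis plant 1. Between the P. grandis plants, 3631 of 18900 contigs with at least 5 CPM in either plant (19.2%) differed at least 4-fold, against 412 contigs (2.60%) in P. costivenia and 93 contigs (0.570%) in P. revoluta. Between P. grandis plant 2 and the P. revoluta plants, 640 and 598 contigs (3.66% and 3.47%) differed that much.

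**Figure D1:**
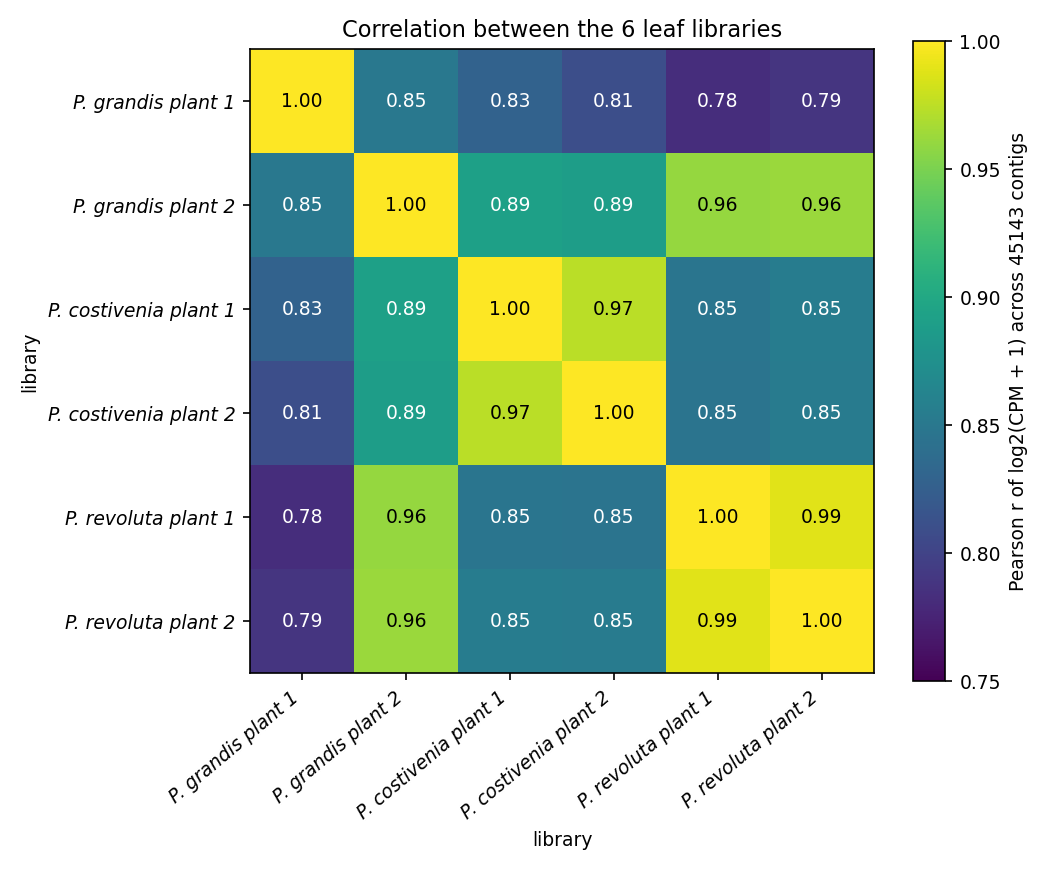
Pearson's r of log2(CPM + 1) across 45143 contigs for each pair of the 6 leaf libraries, shown by number and colour. P. grandis plant 2 stood closer to both P. revoluta plants (0.96) than to P. grandis plant 1 (0.85).

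P. grandis plant 1 held most of the contigs that set 1 library apart. In it, 432 contigs of at least 5 CPM lay more than 10-fold above all other libraries, and 301 contigs lay more than 10-fold below all others. The other 5 libraries had 0 to 17 such contigs above and 0 to 39 below. Every contig with any read had reads in P. grandis plant 1. If the reference was assembled from that plant, transcripts found in another plant alone could not be among the contigs. The numbers above all others would then not be comparable between libraries. The contig with the most counts over all libraries reached 20090 to 25200 CPM in 5 libraries and 44.5 CPM in P. grandis plant 1. The most abundant contig of P. grandis plant 1 stood at 35060 CPM there, at 9727 CPM in P. grandis plant 2 and 6920 CPM in P. costivenia plant 1, and at 155 to 279 CPM in the remaining libraries. The 10 most abundant contigs took 16.2% of the counts of P. grandis plant 1 and 8.59% to 9.71% elsewhere. The first principal component (51.5% of the variance) ran from both P. costivenia plants and P. grandis plant 1 to P. revoluta, with P. grandis plant 2 between, and the second (36.7%) separated P. grandis plant 1. The biological coefficient of variation, the spread between plants beyond counting noise, was 81.9% in P. grandis, 46.4% in P. costivenia and 29.9% in P. revoluta.

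The comparison of P. costivenia with P. revoluta asked which transcripts separate a hyperaccumulator from the non-accumulator. Species, locality and collection date differed along with the phenotype, so these could not be told apart. Pgra_v1_contig_4646 stood at 241 ± 12.9 CPM (SD, n = 2) in P. costivenia and at 0.0534 ± 0.0466 CPM in P. revoluta, where 5 and 1 counts were found, a log2 fold change of 12.32 (SE 1.20, adjusted p = 0.0188 by edgeR). Pgra_v1_contig_1732 stood at 1935 ± 1517 CPM in P. costivenia and at 0.934 ± 0.882 CPM in P. revoluta, a log2 fold change of 11.29 (SE 1.70, adjusted p = 0.0223 by edgeR). In the opposite direction, Pgra_v1_contig_119 stood at 0.0424 ± 0.0307 CPM in P. costivenia, from 3 and 1 counts, and at 259 ± 83.3 CPM in P. revoluta, a log2 fold change of -12.21 (SE 0.77, adjusted p = 0.0179 by edgeR). Pgra_v1_contig_1676 stood at 0.189 ± 0.0254 CPM in P. costivenia and at 976 ± 32.0 CPM in P. revoluta, a log2 fold change of -12.02 (SE 1.76, adjusted p = 0.0214 by edgeR). All 4 contigs lost the call (edgeR) when any 1 of the 4 plants of these species was left out, which left 1 plant in a species. Their log2 fold changes stayed large, at 11.65 to 13.61 for Pgra_v1_contig_4646 and 10.13 to 12.82 for Pgra_v1_contig_1732. They were -13.18 to -11.63 for Pgra_v1_contig_119 and -12.17 to -11.9 for Pgra_v1_contig_1676.

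Across the transcriptome, 3855 contigs were higher and 2426 were lower in P. costivenia than in P. revoluta, 17.6% of the 35660 contigs tested, and 5395 of these 6281 contigs differed at least 4-fold. The median log2 fold change was 3.89 for the higher and -3.69 for the lower contigs, with the 697 and 415 contigs without reads in the lower species at their bound. Called contigs were found at every level of abundance. Among contigs with a mean under 1 CPM, 704 were higher and 506 lower, and among those of 1 to 10 CPM, 1739 were higher and 1143 lower. Among contigs of 10 to 100 CPM, 1258 were higher and 705 lower, and above 100 CPM, 154 were higher and 72 lower. Contigs with reads in all 3 species made up 3158 of the higher and 2011 of the lower contigs. They were also most of the tested contigs, and 15.65% of these 33021 contigs were called. Calls were more frequent where a species had no reads. They made up 50.04% of the 1393 contigs that lacked reads in P. revoluta alone and 35.96% of the 1154 that lacked them in P. costivenia alone. As reads of both species were counted on P. grandis contigs, a difference in sequence may also change counts. This was not tested, and it holds for the 4 contigs above as well. The model of the 4 libraries of these species alone gave 9603 contigs higher and 8842 lower. Library totals in place of TMM moved the median log2 fold change of all tested contigs from -0.001 to -0.29, with 3212 contigs higher and 2986 lower. Without any 1 of the 4 P. costivenia and P. revoluta plants, 0 contigs passed in edgeR, although 7129 to 8788 had an unadjusted p of at most 0.05. Leaving out P. grandis plant 1 gave 9200 higher and 8334 lower contigs, leaving out plant 2 gave 7680 higher and 8263 lower, which turned the balance, and DESeq2 called 7491 higher and 6062 lower with all plants.

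**Figure D2:**
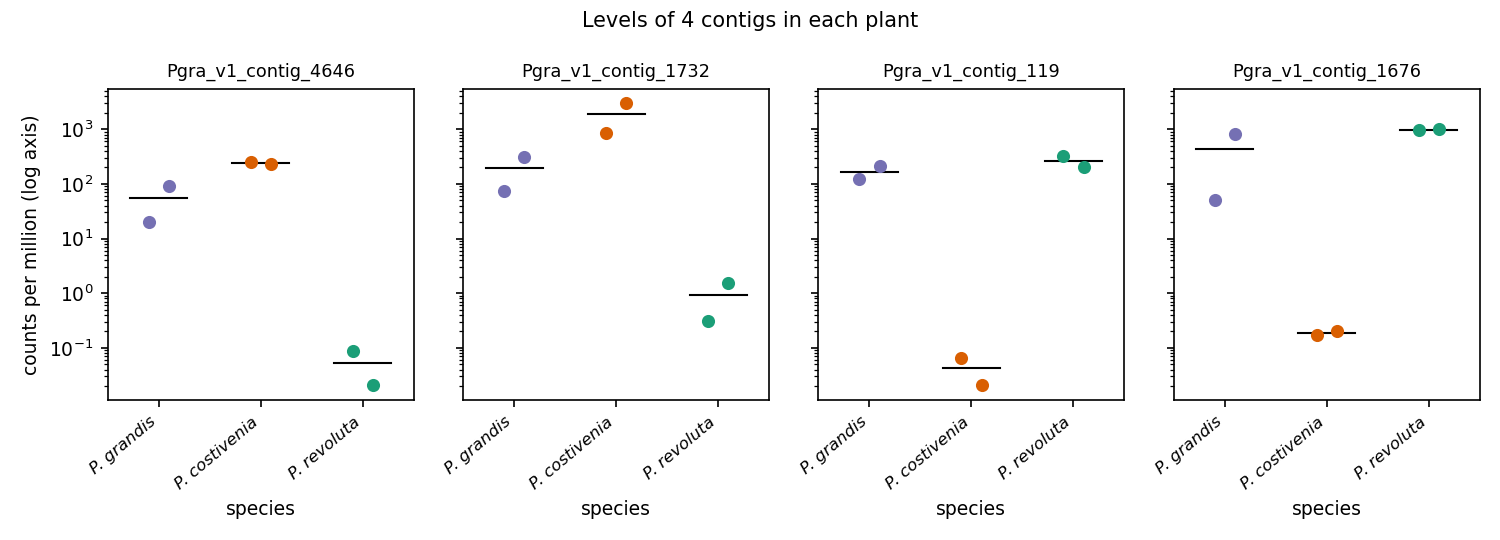
Level in CPM (log axis) of 4 contigs in each plant (points, n = 2 per species), with the mean of each species as a line. Pgra_v1_contig_4646 and Pgra_v1_contig_1732 were lowest in P. revoluta, and Pgra_v1_contig_119 and Pgra_v1_contig_1676 were lowest in P. costivenia.

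The comparison of P. grandis with P. revoluta asked the same of a hyperaccumulator and the non-accumulator from 1 locality. Pgra_v1_contig_4646 stood at 19.7 and 90.5 CPM in the P. grandis plants, above both P. revoluta plants (0.0863 and 0.0205 CPM), with a log2 fold change of 9.89 (SE 1.12) that did not pass the test (adjusted p = 0.0976 by edgeR). Pgra_v1_contig_1732 stood at 74.8 and 311.9 CPM in P. grandis and at 0.311 and 1.56 CPM in P. revoluta, with a log2 fold change of 7.67 (SE 1.48, adjusted p = 0.1001 by edgeR). Pgra_v1_contig_119 and Pgra_v1_contig_1676, which were nearly absent from P. costivenia, were well expressed in P. grandis, at 166 ± 62.4 and 427 ± 532 CPM (SD, n = 2). Their log2 fold changes against P. revoluta were -0.60 (SE 0.46, adjusted p = 0.469 by edgeR) and -1.23 (SE 1.11, adjusted p = 0.529 by edgeR). Omitting a P. grandis plant changed some of these calls in edgeR, but left 1 plant of that species, so only fold changes are given. Without plant 1 or plant 2, the log2 fold change was 10.55 or 8.46 for Pgra_v1_contig_4646 and 8.34 or 6.33 for Pgra_v1_contig_1732. It was -0.35 or -1.02 for Pgra_v1_contig_119 and -0.33 or -4.21 for Pgra_v1_contig_1676. DESeq2, with all plants, called Pgra_v1_contig_4646 (adjusted p = 5.95e-21) and Pgra_v1_contig_1732 (adjusted p = 9.56e-11).

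No contig passed the adjusted threshold for P. grandis against P. revoluta (0 of 35660 in edgeR, smallest adjusted p 0.0790, and 0 in limma-voom). At an unadjusted p of at most 0.05, 6476 contigs were higher and 836 lower in P. grandis, 7312 in all, where chance alone would give 1783. DESeq2 called 5508 contigs, 4992 of them higher and 516 lower. The count rested on the P. grandis plants, since edgeR did call contigs without plant 1 or without plant 2. Those fits left P. grandis with 1 plant and took its spread from the other species. The median log2 fold change of the tested contigs was 0.128 with all plants, 0.023 without plant 1 and 0.381 without plant 2.

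As P. revoluta was the only non-accumulator, its other traits as a species and its match to the reference could not be told apart from accumulation. With that limit, contigs that set P. revoluta apart from both hyperaccumulators came closest to a contrast in nickel accumulation. By the adjusted test there were 0 (edgeR), because 0 passed for P. grandis, and DESeq2 gave 3703, of which 3340 were higher and 363 lower in both hyperaccumulators. In edgeR, such contigs were found without P. grandis plant 1 or without plant 2, in fits that left that species with 1 plant. By size alone, a measure chosen after the data were seen, 159 contigs were at least 4-fold higher in all 4 hyperaccumulator plants than in both P. revoluta plants, and 20 were at least 4-fold lower. The 159 contigs had a median level of 26.8 CPM in the hyperaccumulators and 0.376 CPM in P. revoluta, 15 of them had no reads in P. revoluta, and 90 had at least 10 counts in every library. The 20 contigs had medians of 2.32 CPM in the hyperaccumulators and 31.9 CPM in P. revoluta. Of the 159 contigs, edgeR called 151 in P. costivenia and 0 in P. grandis, and DESeq2 called 158 in both. As the contigs were chosen for this difference in the same plants, these calls are no separate evidence for it. With P. grandis plant 2 left out the numbers were 619 higher and 660 lower in the hyperaccumulators, so the preponderance of higher contigs was lost without that plant. They were 218 and 53 without P. revoluta plant 2, and 1069 and 43 with CPM + 0.1 and all plants.

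The same measure set both plants of P. costivenia apart in 711 contigs, 389 higher and 322 lower than in all other plants, and both plants of P. grandis in 72 contigs, 70 higher and 2 lower. As the contigs were assembled from P. grandis, transcripts absent from its reference plant are missing here. This may have shaped the split for P. grandis and the counts across species, and was not tested. The balance for P. costivenia turned with the scale, to 300 higher and 385 lower under library totals alone and to 743 and 989 with CPM + 0.1. The 12 pairs made of plants of different species gave at most 19 contigs. Without regard to size, 8226 contigs (23.1%) were lower and 7244 (20.3%) were higher in both P. revoluta plants than in all others, where chance gives 6.67% in each direction. For P. costivenia the shares were 21.1% lower and 22.3% higher. For P. grandis they were 7.02% and 10.7%. The 12 pairs of plants of different species had 1.25% to 11.2% in either direction, the highest for P. grandis plant 1 with P. costivenia plant 1 (11.2% lower and 9.61% higher). The count for P. costivenia was 1748 without P. grandis plant 1 and 1161 without P. costivenia plant 1, and the count for P. grandis was 2091 without its plant 2 and 118 without P. costivenia plant 1.

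**Figure D3:**
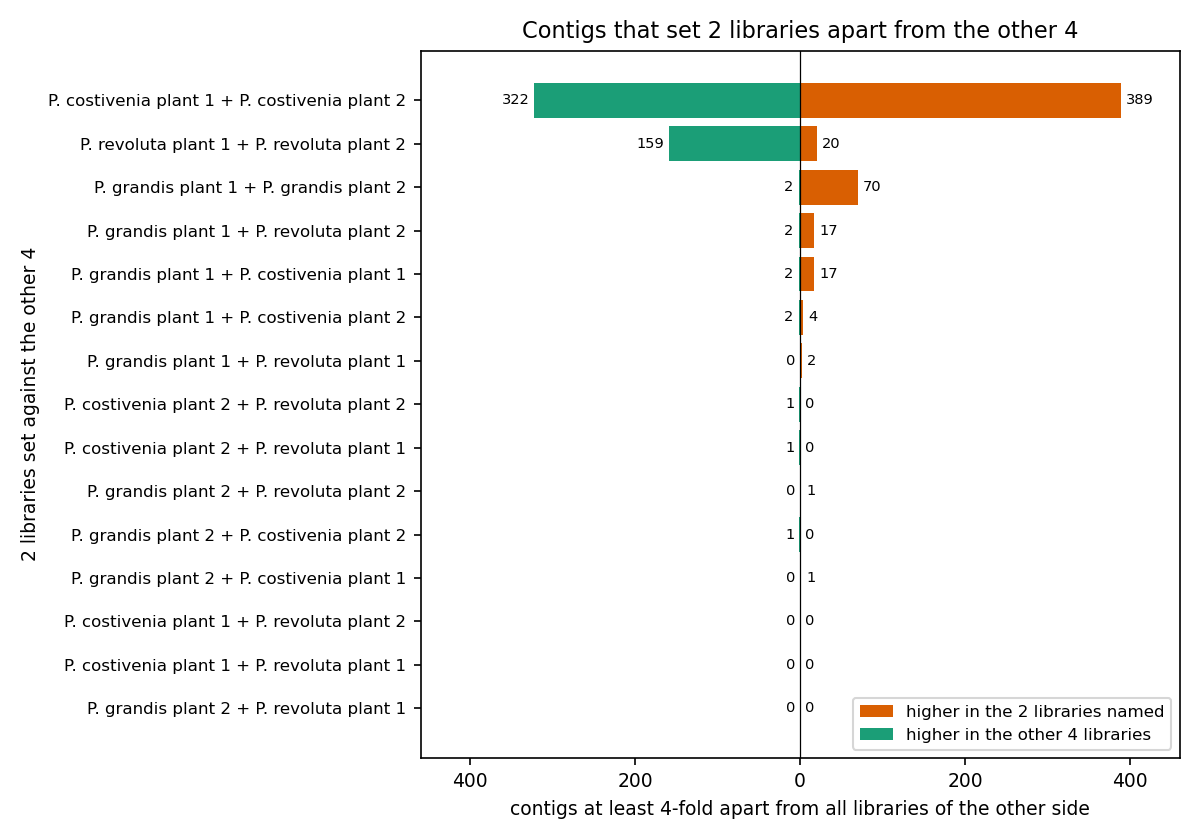
Number of contigs for which both libraries named on the vertical axis lay at least 4-fold above (orange, to the right) or below (green, to the left) all other 4 libraries, for the 15 possible pairs of libraries. The pair of P. costivenia plants gave 711 contigs, that of P. revoluta 179, that of P. grandis 72, and pairs of different species at most 19.

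The fold changes of both hyperaccumulators against P. revoluta were correlated across contigs (r = 0.657, covariance 5.01). Groups simulated without any difference, in which both comparisons shared simulated P. revoluta libraries, gave a correlation of 0.498 and a covariance of 0.533. All libraries were simulated with the same spread for a contig, whereas the real spread was 81.9% in P. grandis, 46.4% in P. costivenia and 29.9% in P. revoluta. The simulated values are therefore only a rough measure of what the shared plants give. At an unadjusted p of at most 0.05 (edgeR), 4066 contigs were higher in both hyperaccumulators and 560 were lower in both. The simulated groups gave 291.5 and 123.8, and independent lists of these sizes would share 1399 and 146.9. Part of the excess may come from the shared P. revoluta plants. The contigs called between P. costivenia and P. revoluta did not place P. grandis on the side of P. costivenia as a whole. Of the 3855 contigs higher in P. costivenia, P. grandis plant 1 lay on its side of the midpoint for 2053 (53.3%) and plant 2 for 1215 (31.5%). Of the 2426 lower contigs, the numbers were 1106 (45.6%) and 259 (10.7%).

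The comparison of P. grandis with P. costivenia gave the difference between hyperaccumulators, without a difference in phenotype but with one in locality. Pgra_v1_contig_119 and Pgra_v1_contig_1676 were higher in P. grandis, by log2 fold changes of 11.61 (SE 0.76, adjusted p = 0.0227 by edgeR) and 10.79 (SE 1.69, adjusted p = 0.0462 by edgeR). Both had been named for their low level in the same P. costivenia plants, which favours a large difference here. The call of Pgra_v1_contig_1676 was lost in limma-voom (adjusted p = 0.0900), against a 2-fold change (0.0637), in the model of the 4 libraries of these species (0.137) and without any 1 of the P. costivenia or P. revoluta plants (0.159 to 0.288), with adjusted p over all alternatives from 1.10e-19 (DESeq2) to 0.288. That of Pgra_v1_contig_119 was lost in the model of the 4 libraries (0.131) and without any 1 of the P. costivenia or P. revoluta plants (0.138 to 0.208), with adjusted p from 5.55e-38 (DESeq2) to 0.208 over all alternatives. Pgra_v1_contig_4646 and Pgra_v1_contig_1732 had log2 fold changes of -2.43 (SE 0.76, adjusted p = 0.129 by edgeR) and -3.62 (SE 1.22, adjusted p = 0.145 by edgeR), which did not pass in edgeR and passed in DESeq2 (adjusted p = 0.00896 and 0.00342). Without P. grandis plant 1 or plant 2, which left 1 plant of that species, the log2 fold change of Pgra_v1_contig_4646 was -1.76 or -3.73. It was 11.87 or 11.31 for Pgra_v1_contig_119 and 11.69 or 7.95 for Pgra_v1_contig_1676. In all, 652 contigs were higher and 304 lower in P. grandis, 2.68% of those tested. The split was 795 to 207 under library totals alone and turned to 571 higher and 656 lower in limma-voom. The median log2 fold change was 5.89 for the higher contigs, with the 193 without reads in P. costivenia at their bound, and -3.13 for the lower. Each fit that left out a plant kept only 1 plant of its species. Without P. grandis plant 1, 4671 contigs were higher and 3957 lower, without plant 2 they were 5333 and 5162, and without any 1 of the P. costivenia or P. revoluta plants 0 passed in edgeR, with 5305 to 6555 at an unadjusted p of at most 0.05. DESeq2 called 7969 contigs with all plants, and edgeR called 0 in the model of the 4 libraries of these species, where 6656 had an unadjusted p of at most 0.05.

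Contigs that differed from both other species by the adjusted test (edgeR) could be found for P. costivenia alone. For P. grandis and P. revoluta the count was bound to be 0, since 0 contigs passed between those species. In P. costivenia, 296 contigs were higher and 588 lower than in P. grandis and P. revoluta alike. The split of these contigs was 201 to 704 under library totals alone and turned to 637 higher and 466 lower in limma-voom, and 0 contigs were left when each pair of species was fitted separately in edgeR, since 0 then passed between P. grandis and P. costivenia. Contigs apart in P. grandis numbered 0 in edgeR, where P. grandis had 7312 contigs against P. revoluta and 9334 against P. costivenia at an unadjusted p of at most 0.05, and 1090 in DESeq2, which gave 5538 for P. costivenia. Without P. grandis plant 1 or plant 2, 8042 or 4589 contigs were apart in P. costivenia and 76 or 6002 in P. grandis. Without any 1 of the other 4 plants, both counts were 0 in edgeR.

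Some contigs had reads in both plants of a species and none in another. P. costivenia had no reads on 654 contigs that had at least 10 counts in both P. grandis plants, and on 490 with such counts in both P. revoluta plants. P. revoluta had none on 829 contigs read in P. grandis and on 942 read in P. costivenia. These contigs were weakly expressed where they were read, with medians of 1.14 to 1.45 CPM, against an upper limit of 0.0316 CPM for P. costivenia and 0.0281 CPM for P. revoluta. As the reference came from P. grandis, 0 contigs lacked reads in P. grandis (198 of P. costivenia and 21 of P. revoluta without P. grandis plant 1), and a contig without reads may be one whose sequence differs in the other species. The counts against P. grandis rose to 5439 in P. costivenia and 3675 in P. revoluta without P. grandis plant 2. Without P. costivenia plant 1 or plant 2, P. costivenia lacked 1250 or 1166 contigs of P. grandis and 975 or 913 of P. revoluta, the latter 1080 without P. revoluta plant 1.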

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

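All tests of explanations given here were chosen only after the result was seen.

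The effect against P. revoluta differed between the hyperaccumulators for 956 contigs, since the test of P. grandis against P. costivenia is also the test of that difference (edgeR, adjusted p at most 0.05). Of the named contigs, Pgra_v1_contig_119 and Pgra_v1_contig_1676 were among these, with differences of the effects of 11.61 and 10.79 on the log2 scale. Both were nearly absent from P. costivenia and present in both other species. They had been named for their low level in these same P. costivenia plants, so the large differences are no separate evidence. Without any 1 of the P. costivenia or P. revoluta plants, 0 contigs passed, and without P. grandis plant 1 or plant 2, 8628 or 10495 did.

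P. grandis plant 2 was closer to P. revoluta (r = 0.960 and 0.963) than to P. grandis plant 1 (0.851), but a mislabelled P. revoluta plant is argued against by contigs read in P. grandis plant 1 and both P. costivenia plants but with at most 1 count in P. revoluta plant 1: 88.9% of 306 (95% interval 84.8% to 92.2%) reached 10 counts in P. grandis plant 2, against 2.94% in P. revoluta plant 2. RNA of P. grandis plant 1 mixed with that of P. revoluta is argued against by contigs abundant in P. grandis plant 1 and nearly unread in the other species, of which 59.5% of 163 (51.6% to 67.1%) had under 10 counts in plant 2. The reference was built from 1 P. grandis plant. That contigs unread in some libraries made plant 2 look closer to P. revoluta is argued against by contigs with at least 50 counts in all 6 libraries. Over these, r was 0.729 between the P. grandis plants, and 0.931 and 0.942 between plant 2 and P. revoluta. An unequal match of the plants' reads to contigs read in all libraries stays open, because this selection does not remove it. RNA of another P. grandis plant mixed with that of P. revoluta stays open, because no unmixed library of that plant was analysed: contigs read in P. costivenia and nearly unread in P. revoluta had a median of 26.0% of the plant 1 level, against 98.6% for contigs read in P. revoluta but not P. costivenia. Differences between individual plants, in state or in descent, also stay open and were not tested.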

How the results depend on the processing

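The alternatives to the 4-fold counts, the joint omission of P. grandis plant 2 and P. revoluta plant 2, the omission of contigs shared by P. grandis plant 1 and P. revoluta plant 2 alone, and the limit of 3 counts were chosen after seeing the data. In the order P. grandis against P. revoluta, P. costivenia against P. revoluta, P. grandis against P. costivenia, then contigs apart in P. revoluta, P. grandis and P. costivenia, the counts by edgeR were 0, 6281, 956, 0, 0 and 884. DESeq2 gave 5508, 13553, 7969, 3703, 1090 and 5538. RLE, totals alone, limma-voom, no filter, thinning and reads in all 6 libraries left P. costivenia against P. revoluta between 5321 and 6258. Without a filter, P. grandis against P. revoluta gave 16, and 13 and 7 contigs were apart in P. revoluta and P. grandis. With reads in all 6 libraries, P. grandis against P. revoluta gave 1, P. grandis against P. costivenia 635, and 1 and 583 contigs were apart in P. revoluta and P. costivenia. A mean of at least 10 CPM, which leaves fewer contigs, gave 1893 for P. costivenia against P. revoluta, 594 for P. grandis against P. costivenia and 528 apart in P. costivenia. The test against a 2-fold change gave 3123, 177 and 167 for these, and an adjusted p of 0.01 gave 0, 0 and 0. With the 4 libraries of each pair they were 18445, 0 and 0. The common coefficient of variation was 60.3% in the model of all 6 libraries and 39.3% over the P. costivenia and P. revoluta libraries alone. With P. grandis plant 2 and P. revoluta plant 2 left out, P. grandis against P. revoluta gave 6695, P. grandis against P. costivenia 6840, and 3090, 2941 and 2172 contigs were apart in P. revoluta, P. grandis and P. costivenia. Except where named, the cause was not tested. Of the 6281 contigs called for P. costivenia against P. revoluta and the 956 for P. grandis against P. costivenia, 0 were called with the opposite sign under an alternative. All alternatives used the same plants, and those that called 0 contigs could not show an opposite sign. For the 4 named contigs, 191 of the alternative values kept their side of the threshold, 36 no longer passed, 13 newly passed and 0 changed sign. These contigs were chosen for large fold changes, so a change of sign was unlikely.

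Leaving out each library in turn gave 0 to 15201 contigs for P. grandis against P. revoluta, 0 to 17534 for P. costivenia against P. revoluta and 0 to 10495 for P. grandis against P. costivenia. Contigs apart in P. revoluta ranged from 0 to 8554, in P. grandis from 0 to 6002 and in P. costivenia from 0 to 8042. The high ends came without P. grandis plant 1 for P. costivenia against P. revoluta and for contigs apart in P. costivenia, and without plant 2 for the others. A species left with 1 plant was assumed to vary like the others. Contigs without reads in P. costivenia and read in P. grandis ranged from 654 to 5439, and read in P. revoluta from 490 to 1080. Contigs without reads in P. revoluta and read in P. grandis ranged from 829 to 3675. Those without reads in P. grandis ranged from 0 to 198 for P. costivenia and 0 to 21 for P. revoluta, the high ends without P. grandis plant 1. The 4-fold counts ranged from 91 to 2091 in P. grandis, 739 to 1748 in P. costivenia and 207 to 1279 in P. revoluta.

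The plant numbers did not pair the samples: deviations of same-numbered plants correlated at 0.108 for P. grandis and P. costivenia, -0.254 for P. grandis and P. revoluta and -0.0133 for P. costivenia and P. revoluta. With the plant number as a replicate block, edgeR called 976 contigs for P. costivenia against P. revoluta, 0 for P. grandis against P. costivenia and 0 apart in P. costivenia, where 12617 and 7883 contigs had an unadjusted p of at most 0.05 in the first and second. The calls of Pgra_v1_contig_119 and Pgra_v1_contig_1676 in P. grandis against P. costivenia were not made with the block (adjusted p = 0.0828 and 0.0981).

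With a minimum of 50 counts, P. costivenia lacked 227 contigs of P. grandis and 259 of P. revoluta, and P. revoluta lacked 208 of P. grandis and 451 of P. costivenia. With at most 3 counts in place of 0 the numbers were 1431, 1216, 1579 and 1649. With log2(CPM + 0.1), r was 0.829 between the P. grandis plants, 0.951 and 0.942 between P. grandis plant 2 and the P. revoluta plants, 0.966 in P. costivenia and 0.981 in P. revoluta. Over the tested contigs alone these were 0.817, 0.949, 0.952, 0.968 and 0.986. With CPM + 0.1 the 4-fold counts were 346 in P. grandis, 1732 in P. costivenia and 1112 in P. revoluta. With reads in all 6 libraries, that of P. grandis was 39. With P. grandis plant 2 and P. revoluta plant 2 left out they were 2403 in P. grandis and 1581 in P. revoluta. Thinning to equal depth changed no call count by over 1.5 times.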

Other observations

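The tests of carry-over and of another organism, and the use of the scaling alternatives to weigh the split of higher and lower contigs, were chosen only after the result was seen; the alternatives themselves were not.

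A set of 723 contigs had at least 10 counts in P. grandis plant 1 and P. revoluta plant 2 and at most 3 counts in each of the other 4 libraries. The same measure gave 251 contigs for P. grandis plant 1 with P. grandis plant 2, 66 and 57 with the P. costivenia plants and 27 with P. revoluta plant 1. The 723 contigs held 0.212% of the counts of P. grandis plant 1 and 0.0540% of those of P. revoluta plant 2, with a median ratio of counts of 24.4%. Carry-over of reads between these libraries is argued against by the 20 most abundant contigs of P. grandis plant 1, of which 9 lay more than 10-fold below that ratio in P. revoluta plant 2 and the lowest reached 0.00217% (19 counts against 876584). RNA of another organism on both leaves may account for the 723 contigs and could not be tested, since contig sequences were not analysed here, and no biological explanation was tested.

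Higher contigs outnumbered lower ones between P. costivenia and P. revoluta, 3855 to 2426 (61.4%). Whether scaling between libraries made the excess was left open by the values: library totals in place of TMM gave a share of 51.8% and RLE size factors 59.9%. With TMM kept, the share also fell to 52.1% (9603 higher, 8842 lower) in the model of the P. costivenia and P. revoluta libraries alone. With the P. grandis libraries kept, the share was 55.3% in DESeq2 and 54.4% with a mean of at least 10 CPM. It was 63.3% in limma-voom and 64.9% without a low-count filter. The excess thus also varied with the model and with the contigs tested, for reasons that were not tested. A lower scale moves all contigs the same way, so the fall under library totals does not show which scale is right. More transcripts raised in P. costivenia also stay open, untested, because the level of total mRNA was not measured.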
